A study of Drosophila melanogaster with 18 samples.

How the data were processed

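RNA of whole Drosophila melanogaster embryos was hybridised to 18 Affymetrix arrays with 13966 probe sets each, in 9 groups of 2 arrays. Per the labels, RNA came from about 200 to 700 embryos per sample, collected over 2 h, aged at 25 °C and frozen. The deposited table holds linear probe-set signal as intensity, which the authors made with arrays scaled to a common mean: the mean after trimming the highest and lowest 2% of probe sets lay between 495.5 and 497.8 on all 18 arrays. The software that summarised probes into probe sets, its version and its settings are not given in the sources used here. No detection calls were used, and the table holds 0 control probe sets with the AFFX prefix, so the planned check of RNA quality from such probe sets was not run. For arrays the number of arrays limits the precision, and n is 2 per group throughout.

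The groups, 11 comparisons, gene lists, named-genes rule, tests and most alternatives were set before the data were examined. Array medians differed by 0.244 on the log2 scale, above the limit of 0.1 set for adding quantile normalization, so the arrays were quantile normalized. Values under the 20th percentile of all values were set to that floor (signal 47.5, or 5.57 on the log2 scale) and all values were log2 transformed. The 30% of probe sets with the lowest mean were left out. Of the probe sets, 12443 map to 1 gene, 327 to several and 1196 to none in the annotation used here. For each gene the probe set with the highest mean was kept, which left 8975 units to test: 7927 named genes and 1048 probe sets without a single gene. Genome coordinates were not used, apart from the chromosome of each gene.

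Differences between groups were tested in R 4.3.3 with limma 3.58.1, in a fit of 9 group means to all 18 arrays with eBayes(trend=TRUE), which gave 9 residual and 6.16 prior degrees of freedom. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 8975 units of each comparison, with a threshold of 0.05. Errors of log2 changes are standard errors (SE) from this fit, and errors of signals are standard deviations (SD) of 2 arrays. The replicate numbers of the samples gave no evidence of pairing, so no replicate block was used. With 2 arrays per group, no regrouping of samples was counted.

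Gene lists were written from general knowledge, and 26 of them had at least 5 measured members. Each was tested with camera (limma, preset correlation 0.01) against all other units, adjusted over the 26 lists of a comparison, and again with an estimated correlation. As a further alternative set beforehand, fry (limma) tested whether the genes of a list move, on balance, one way, which does not compare the list with other genes. Counts of list members that passed are given over all genes tested and adjusted over the list alone. Named genes are, per comparison, E2f1, E2f2, Dp and Rbf; the 6 largest changes in each direction among named genes that passed and whose arrays did not overlap; the 2 largest of any symbol; and up to 4 members with the smallest p of each list described. Genes named outside this rule are marked as chosen after their values were seen. A fold against a group with both arrays at the floor is given as a lower bound. Some members stand on more than 1 list, such as Dp, E2f2, Rbf and Caf1-55.

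A stage index was computed for each array as the mean log2 signal of the 300 genes with the largest rise between the 2 control ages minus that of the 300 with the largest fall, scaled so that the control means are 0 and 1. Genes of the cell cycle, ribosomal and digestion lists and probe sets above 10000 in deposited signal were kept out of it. Genes of other lists, such as muscle and epidermis, were not, so the loss of such a list with interpolated controls may be partly built in. The correlation and covariance across genes of 2 comparisons were set against 100 simulated data sets with the same shared controls. Counts of shared genes were set against independent calls, which do not allow for shared controls. The alternatives were the deposited scaling, median centring, a log2 offset of 50, no floor, no filter or a 50% filter on dim probe sets, every probe set tested, limma without the trend or with robust eBayes, a replicate block, a fold minimum of 1.5, a fit of the groups compared alone, and each array left out in turn. Probe sets above 10000 left out, controls interpolated to the stage index, and the 4 manipulated genes left out of the lists that hold them were added after seeing the data. The steps were tested on simulated data: 34% of genes changed 2-fold, 63.3% of those changed 4-fold and 93.9% of those changed 16-fold were recovered, and 5 unchanged genes (3.8% of the calls) were called. Noise in these data was independent between genes and equal in all groups. The rates need not hold where genes vary together or the control varies more.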

Results

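Transcript levels were measured in whole fly embryos at 2 ages. At 8 to 10 h of development the groups were a control (the Arm-Gal4 driver crossed to yw), embryos in which the same driver expressed E2f1 with Dp, E2f2 with Dp, an E2f1 fragment that lacks the DNA-binding domain (a dominant negative form), or Rbf1, and null mutants of Dp and of E2f1. At 14 to 16 h the groups were the control cross and E2f1 mutants. E2f1 and E2f2 are the fly's activating and repressing E2F transcription factors, Dp is their dimerisation partner, and Rbf1 (gene symbol Rbf) is a retinoblastoma-family protein that binds E2F. Mutants at 8 to 10 h were picked by an automated embryo sorter from stocks with fluorescent balancer chromosomes, and those at 14 to 16 h by hand. The control came from a driver cross and the mutants from mutant stocks. Stock background and driver therefore cannot be told apart from genotype in any comparison of a mutant with the control. Deposited array medians ranged from 209.15 to 247.75. The correlation across genes between the arrays of a group, in which genes are not independent replicates, ranged from 0.894 in the control at 8 to 10 h to 0.951 in the control at 14 to 16 h. Every group holds 2 arrays, and the labels do not say whether the 2 RNA samples of a cross came from separate collections, so p-values measure only the spread between these samples.

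Of the manipulated transcripts E2f2, Dp and Rbf changed with the genotype by limma, and E2f1 did not pass in any manipulated group against its control. E2f2 had a signal of 21230 ± 318 (SD, n = 2) in E2f2/Dp embryos against 2178 ± 281 in the control. Dp was 5629 ± 409 in E2f1/Dp embryos, 4380 ± 137 in E2f2/Dp embryos, 587.7 ± 128 in Dp mutants and 1869 ± 312 in the control. Rbf was 2060 ± 216 in Rbf1 embryos and 292.3 ± 72.9 in the control. E2f1 was 9617 ± 3770 in E2f1/Dp embryos, 4420 ± 398 with the E2f1 fragment, 568.6 ± 343 in E2f1 mutants and 1990 ± 940 in the control, all at 8 to 10 h, and none of these 3 differences from the control passed. At 14 to 16 h it was 520.8 ± 103 in E2f1 mutants and 592.2 ± 0.731 in the control (log2 change -0.20, adjusted p = 0.912), so the transcript level does not tell the mutants from the control at that age. The E2f1 probe set also read 3221 and 13650 on the 2 Rbf1 arrays, a difference from the control that did not pass either. On the same arrays Rbf read 2213 and 1908, Dp 1687 and 1680 and PCNA 3611 and 3876. Rbf on replicate 2 lay far above the control (292.3 ± 72.9), E2f1/Dp (337.1 ± 83.6) and fragment embryos (375.1 ± 30.4), which argues against a swap with these groups. Its E2f1 signal exceeded the mean of E2f1/Dp embryos (9617) while Dp stayed near the control (1869 ± 312), which argues against a mix with E2f1/Dp embryos. The cause of its E2f1 signal stays unknown, which limits what the Rbf1 group stands for. PCNA, the sliding clamp of DNA replication, had its highest group mean in E2f1/Dp embryos (10850 on each array) and lower ones in Dp mutants (1992 ± 233) and E2f1 mutants at 8 to 10 h (1143 ± 106) than in the control (5239 ± 759).

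**Figure D1:**
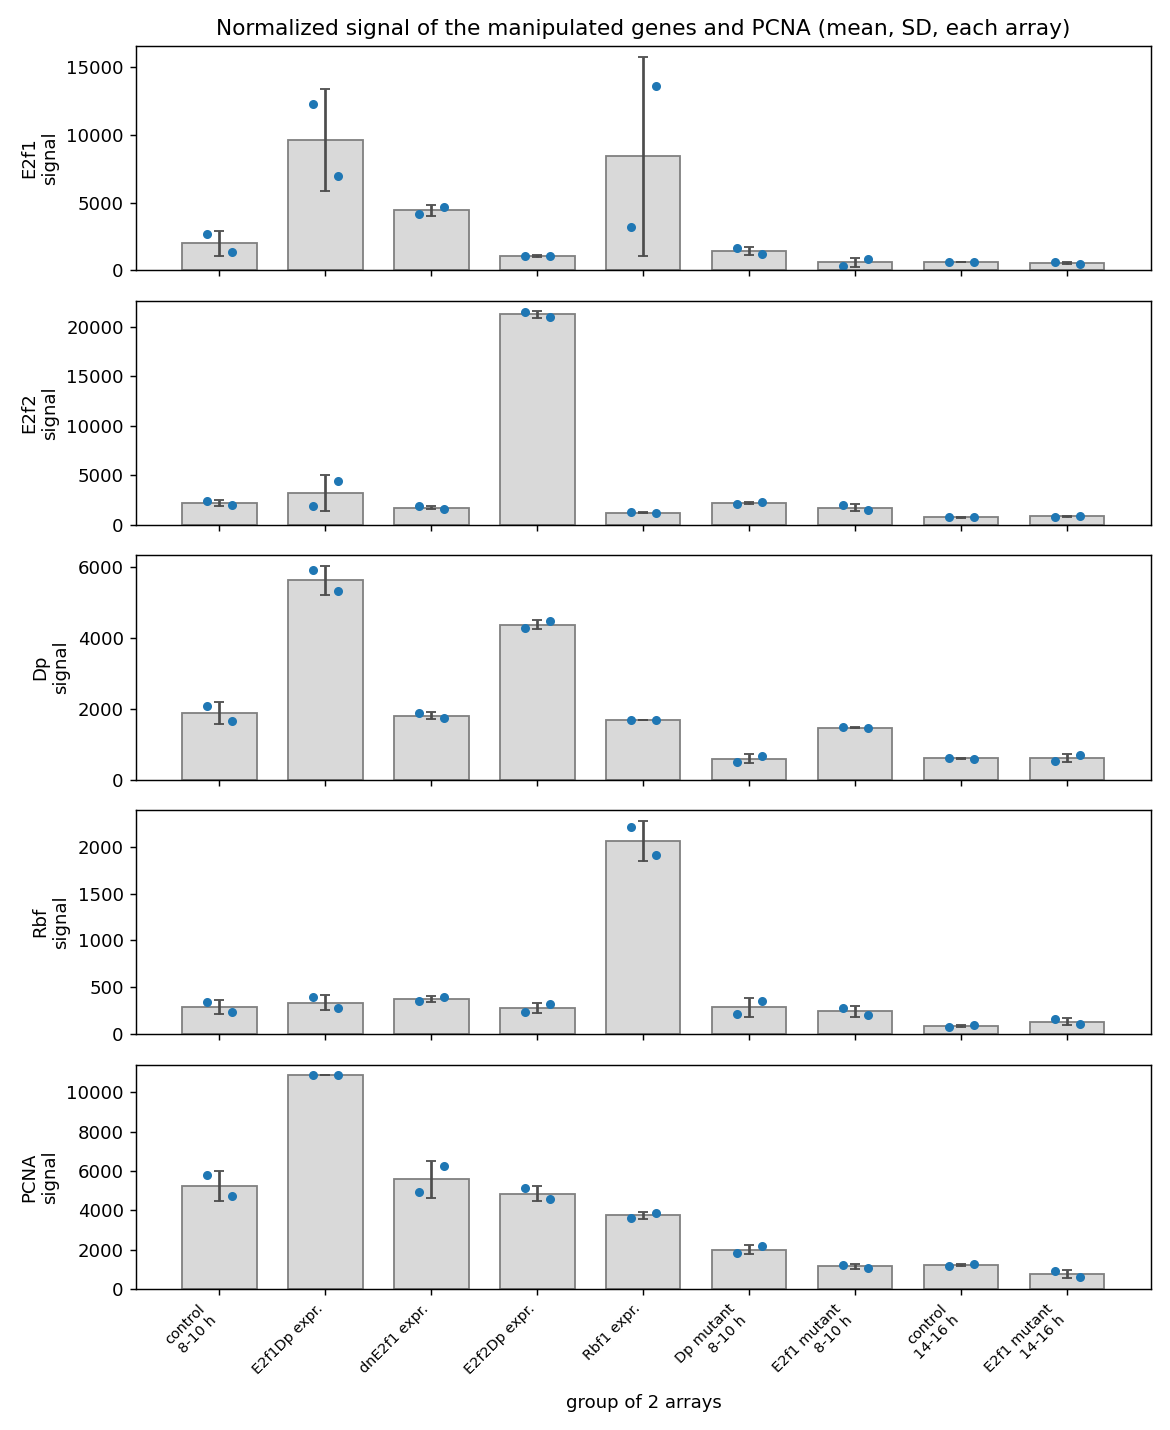
Normalized signal (linear axis from 0) of E2f1, E2f2, Dp, Rbf and PCNA in the 9 groups: bars are means of 2 arrays, error bars SD, points single arrays. E2f2 stands at 21230 in E2f2/Dp embryos and PCNA at 10850 in E2f1/Dp embryos and 1143 in E2f1 mutants at 8 to 10 h.

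The stage index and the brightness of the arrays also differed between groups. The index is a score of transcripts, and no staging of embryos was used here. Tissue genes such as those of muscle were not kept out of it. A change of such genes with genotype would therefore move it too. The stage index, 0 in the 8 to 10 h control (SD 0.074) and 1 in the 14 to 16 h control, was 0.249 ± 0.121 in Dp mutants (0.334 and 0.164 on the 2 arrays), 0.219 ± 0.024 in E2f1 mutants at 8 to 10 h, 0.139 in E2f1/Dp embryos, 0.062 in E2f2/Dp embryos, 0.033 in Rbf1 embryos, -0.058 with the E2f1 fragment and 0.875 ± 0.007 in E2f1 mutants at 14 to 16 h. The deposited signal exceeded by 0.1% of probe sets was 15967 and 13370 on the Rbf1 arrays and up to 28663 on the other control and overexpression arrays of 8 to 10 h. It lay between 32090 and 46351 on the mutant and 14 to 16 h arrays.

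**Figure D2:**
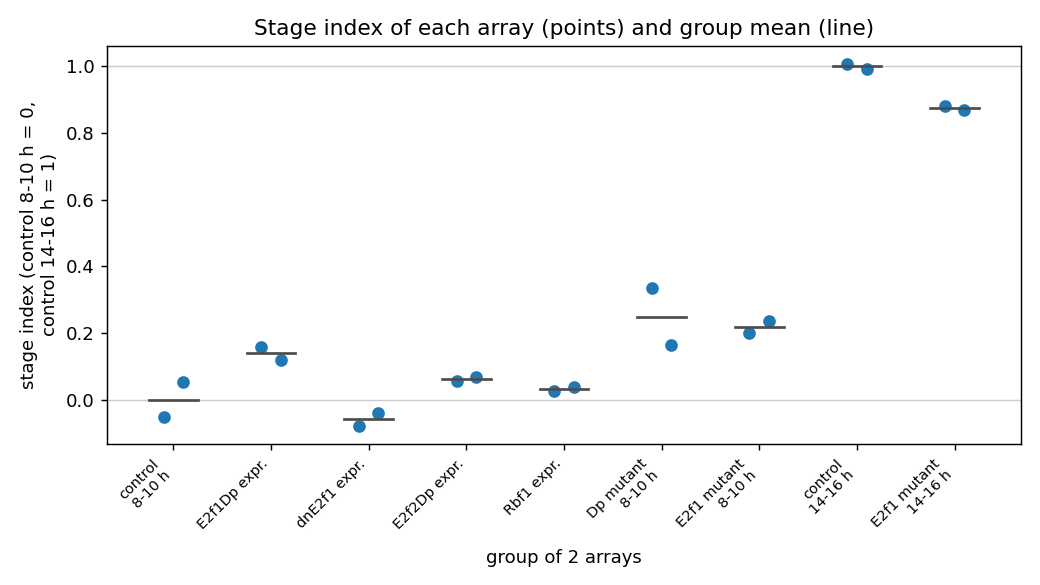
Stage index (no unit; control means at 0 and 1) of each of the 18 arrays as points, with lines at group means. Dp mutants (0.249) and E2f1 mutants (0.219) of 8 to 10 h lie above their control, and E2f1 mutants of 14 to 16 h (0.875) below theirs.

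Development of the control from 8 to 10 h to 14 to 16 h asks which genes change with age in these embryos. Cuticle genes rose: TwdlG, of the Tweedle family of cuticle proteins, rose 34.7-fold (log2 change 5.12 ± 0.49, SE, adjusted p = 1.77e-06), and a probe set of Cht6, a chitinase, rose at least 32.5-fold from a control at the floor. Another probe set of Cht6 read 0.19 on the log2 scale (adjusted p = 0.778). Among the largest falls, Tom fell 39.4-fold (log2 change -5.30 ± 0.18, adjusted p = 3.19e-11), E(spl)m5-HLH, of Notch signalling, at least 35.5-fold and a probe set of Ocho at least 77.2-fold. Another probe set of Ocho read -1.08 (adjusted p = 0.0108). E2F network transcripts were lower at the later age: E2f2 (log2 change -1.5), Dp (-1.63) and Rbf (-1.72) fell. E2f1 fell by 1.66 on the log2 scale (adjusted p = 0.0204), a call lost without replicate 1 of the 8 to 10 h control (adjusted p = 0.184) or without replicate 1 (0.0758) or 2 (0.0741) of the 14 to 16 h control. Over all genes 3876 of 8975 changed, 1579 higher and 2297 lower, and the count without single arrays was 2837 to 3664. Of 14 measured maternal markers, a set chosen after seeing the data, 2 were higher at the later age, smg (1.46 ± 0.33, adjusted p = 0.00246) and bcd (1.19 ± 0.35, adjusted p = 0.0123). The median of the set was 0.2 (SD 0.94, 9 positive). Of 117 named calls, 105 passed without each array in turn.

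Tissue genes rose and proliferation genes fell between the control ages. The median of all genes moved by -0.188 on the log2 scale (-0.16 with the deposited scaling and -0.242 with median centring), so list medians of this comparison are given relative to it. Muscle markers rose (15 of 18 members; 15 higher and 1 lower adjusted over the list alone, relative median 2.98, camera adjusted p = 1.91e-07), among them Mlc1 (log2 change 2.89 ± 0.35) and Prm (4.02 ± 0.50), both of the contractile apparatus, adjusted p = 0.0605 with an estimated correlation. Digestion genes of the midgut rose (20 of 24, 21 adjusted over the list alone, relative median 2.40, adjusted p = 1.26e-07, and adjusted p = 0.0984 with an estimated correlation). Epidermis and cuticle genes (15 of 23 higher and 2 lower, relative median 1.88), neuroblast markers (13 of 16 lower; -1.48), proteasome subunits (20 of 29 lower; -0.79) and cohesion and chromatin assembly genes (13 of 18 lower; -1.18) were called by camera also with an estimated correlation, at adjusted p = 0.0379, 0.0169, 0.042 and 0.0447. Mitosis genes (29 of 37 lower and 1 higher, relative median -1.07), origin licensing and firing genes (13 of 19 lower; -1.61) and replication fork genes (16 of 19 lower; -1.61) were called lower, with adjusted p = 0.123, 0.0827 and 0.0984 with an estimated correlation.

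Further lists were called between the control ages. Glycolysis genes were higher (8 of 8, relative median 1.81), as were immune response genes (7 of 8, 1.76), neuronal markers (7 of 10 with 1 lower; 1.80) and heat shock and stress genes (7 of 13 with 1 lower; 1.22). With an estimated correlation these have adjusted p = 0.0605, 0.0605, 0.0984 and 0.0605. Haemocyte markers (8 of 18 higher and 3 lower, relative median 0.56) were called at adjusted p = 0.0428, a call lost with an estimated correlation (adjusted p = 0.264), without replicate 1 of the 8 to 10 h control (adjusted p = 0.258), without a filter on dim probe sets (0.0855) and with bright probe sets left out (0.148). dREAM subunits, of the repressor complex that holds E2f2 and Dp (8 of 10 lower; -1.49), G1 and S regulators (11 of 15 lower; -1.31), early patterning genes (12 of 21 lower and 1 higher; -1.02) and DNA damage genes (11 of 23 lower; -0.87) were called lower, with adjusted p = 0.0605, 0.0605, 0.0605 and 0.0897 with an estimated correlation. With the lowest 50% of probe sets left out the immune, neuronal and DNA damage calls were lost (0.0713, 0.0806 and 0.215). Not set relative to all genes, the median of the haemocyte list was 0.37, and 0.94 without replicate 2 of the 8 to 10 h control. That of the patterning list was -1.21, and -0.75 without replicate 1. That of the G1 and S list was -1.5, and -0.87 with E2f1, E2f2, Dp and Rbf left out of it. Nucleotide synthesis (camera adjusted p = 0.344), tracheal (0.381), ribosomal protein (0.624), ecdysone (0.713), germline (0.755), fat body (0.755), apoptosis (0.755) and glial (0.773) lists were not called.

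Expression of E2f1 with Dp asks which genes respond to more of the activating E2F. The gene phu rose 5.28-fold, from 1101 ± 354 to 5659 ± 27.6 (log2 change 2.40 ± 0.26, adjusted p = 0.00103), and Dp rose 3.03-fold (1.60 ± 0.19, adjusted p = 0.00147). CG14312 fell (-2.21 ± 0.27, adjusted p = 0.00147). These 3 calls held without each array in turn. PCNA (1.06 ± 0.20) and PolA1, the catalytic subunit of DNA polymerase alpha (1.07 ± 0.20), each had an adjusted p of 0.0651, and RnrL, of ribonucleotide reductase (1.37 ± 0.28), and the deoxynucleoside kinase dnk (1.05 ± 0.21) each had 0.0914. In all, 8 genes passed, 6 higher and 2 lower (767 at an unadjusted p under 0.05), and the count was 100 without replicate 2 of the control and 15 without replicate 2 of E2f1/Dp. MsrA, CG15117 and Slc45-1 also passed but not without replicate 1 of the control (adjusted p = 0.161, 0.129 and 0.0532). Slc45-1 and CG15117 were also lost without replicate 1 of E2f1/Dp (0.0673 and 0.119), and MsrA and CG15117 without replicate 2 (0.192 and 0.121).

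As lists, replication genes were called higher with E2f1/Dp by camera, which sets a list against all other genes. By fry, which tests whether a list's genes move one way on balance, all 7 list calls of this comparison were lost (adjusted p = 0.147 to 0.304). Of 19 replication fork genes 18 had a positive log2 change (median 0.44, camera adjusted p = 1.93e-06, adjusted p = 0.367 with an estimated correlation), with 0 passing limma over all genes and 4 adjusted over the list alone, and of 19 origin licensing and firing genes 16 did (median 0.33, adjusted p = 0.0145, adjusted p = 0.386 with an estimated correlation). Cohesion and chromatin assembly genes (median 0.33, adjusted p = 0.0153) and G1 and S regulators (0.21, adjusted p = 0.0133) were also called higher, each at adjusted p = 0.367 with an estimated correlation. The G1 and S list holds the expressed genes E2f1 (2.30) and Dp (1.60). With E2f1, E2f2, Dp and Rbf left out of it, an alternative added after seeing the data, its median was 0.14 (adjusted p = 0.416). Without replicate 2 of the control all 4 calls were lost: the fork and origin medians were 0.1 and -0.04 (adjusted p = 0.236 and 0.962), and the cohesion and G1 and S medians 0.26 and 0.24 (adjusted p = 0.537 and 0.41). Muscle markers (median 0.60, adjusted p = 1.23e-04), digestion genes (0.62, adjusted p = 8.27e-05) and immune response genes (0.24, adjusted p = 0.0274) were called higher, at adjusted p = 0.367, 0.374 and 0.374 with an estimated correlation. These had, without replicate 1 of the control, adjusted p = 0.0748, 0.252 and 0.457. Without replicate 1 of E2f1/Dp the origin, G1 and S, cohesion, digestion and immune lists had adjusted p = 0.276, 0.114, 0.276, 0.25 and 0.333. Of the calls that were kept, the fork, origin and G1 and S medians were 0.92, 0.78 and 0.39 without replicate 1 of the control, and the digestion and immune medians 1.11 and 0.71 without replicate 2. Without replicate 2 of E2f1/Dp the fork, origin, digestion and immune medians were 0.7, 0.54, 0.94 and 0.45. The cohesion call was lost with median centring (adjusted p = 0.0741), and the immune call without a filter on dim probe sets (0.159) or with the lowest 50% left out (0.466). The stage index of these embryos was 0.139, and with the control interpolated to it the muscle and immune calls were lost (adjusted p = 0.0989 and 0.286).

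Expression of E2f2 with Dp asks the same of the repressing E2F. E2f2 itself rose 9.79-fold (log2 change 3.29 ± 0.28, adjusted p = 5.12e-05) and RpL28, a ribosomal protein, rose 2.62-fold (1.39 ± 0.17, adjusted p = 0.00134), and both held without each array. Dp rose (1.24 ± 0.19, adjusted p = 0.0186), and the adjusted p was 0.125 and 0.158 without replicates 1 and 2 of E2f2/Dp and 0.157 with median centring. Osi20 fell (-3.04 ± 0.50) and Cpr49Ac, a cuticle protein, rose at least 6.74-fold, both at adjusted p = 0.0279, and neither held without replicate 1 of the control (0.242 and 0.149) or replicate 1 (0.345 and 0.059) or 2 (0.0808 and 0.244) of E2f2/Dp. In all 7 genes passed, 5 higher and 2 lower (790 at an unadjusted p under 0.05), with 194 without replicate 2 of the control and 3 without replicate 2 of E2f2/Dp. Neither Osi20 nor Cpr49Ac is particular to E2f2/Dp. Against the same control arrays Osi20 was also called lower with the E2f1 fragment (-3.85), with Rbf1 (-2.29) and in Dp mutants (-3.27). Mitosis genes were called lower (median -0.36, 7 of 37 positive, camera adjusted p = 3.2e-04, adjusted p = 0.889 with an estimated correlation), with 0 passing limma over all genes and 1 lower adjusted over the list alone. Without replicate 1 of the control their median was -0.04 (adjusted p = 0.632), without replicate 2 it was -0.6, and by fry the adjusted p was 0.505.

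Set against each other, the 2 overexpressions ask where the E2Fs act differently. Relative to E2f2/Dp embryos, E2f1/Dp embryos had 7.96-fold more phu (log2 change 2.99 ± 0.26, adjusted p = 2.96e-05), less E2f2 (-2.87 ± 0.28, adjusted p = 1.07e-04) and less RpL28 (-1.91 ± 0.17, adjusted p = 2.96e-05), and these 3 calls held without each array. PCNA was higher (1.16 ± 0.20, adjusted p = 0.0244), a call lost without replicate 1 of E2f1/Dp (adjusted p = 0.115) or replicate 1 (0.0931) or 2 (0.121) of E2f2/Dp, or with median centring (0.0603). In all 27 genes passed, 16 higher and 11 lower, and the count was 10 without replicate 1 and 74 without replicate 2 of E2f1/Dp, and 9 without either E2f2/Dp array. For CG32365 (-2.74) other probe sets read 0.95 and -0.12. Replication fork genes were higher in E2f1/Dp embryos (1 of 19 passed and 6 adjusted over the list alone, median 0.74, camera adjusted p = 8.96e-08, adjusted p = 0.259 with an estimated correlation), as were all 19 origin genes in sign (median 0.54, adjusted p = 2.17e-05, adjusted p = 0.263 with an estimated correlation) and muscle markers (0.76, adjusted p = 1.36e-05, adjusted p = 0.263 with an estimated correlation). Mitosis (median 0.50), cohesion (0.39), digestion (0.36) and DNA damage lists (0.17) were called higher at adjusted p = 2.17e-05, 0.00181, 0.0117 and 0.0189, with adjusted p = 0.485, 0.259, 0.76 and 0.283 with an estimated correlation. All 4 were lost without replicate 1 of E2f1/Dp (adjusted p = 0.142, 0.0506, 0.682 and 0.185), and the DNA damage list also without replicate 2 of E2f2/Dp (0.131) or with the lowest 50% of probe sets left out (0.446). The digestion and DNA damage medians were 0.79 and 0.39 without replicate 2 of E2f1/Dp, and the latter 0.36 without replicate 1 of E2f2/Dp. By fry the origin, muscle, mitosis, DNA damage and digestion calls were lost (adjusted p = 0.089, 0.089, 0.217, 0.123 and 0.543).

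The E2f1 fragment asks what a dominant negative E2f1 changes. Among the largest falls were cuticle genes: TwdlN fell from 8514 ± 1940 to 575.4 ± 710 (log2 change -4.90 ± 0.78, adjusted p = 0.00456), and a probe set of obst-E, which binds chitin, fell at least 14-fold. Other probe sets of these genes read -2.62 for TwdlN (adjusted p = 0.0335) and -0.82 for obst-E (adjusted p = 0.77). Cpr49Ac, a cuticle protein, rose at least 8.51-fold (adjusted p = 0.00295), a call that held without each array. The rise of Cpr49Ac is not particular to the fragment. Against the same control, at the floor, it was also called higher in E2f2/Dp embryos (2.75), Dp mutants (2.81) and E2f1 mutants of 8 to 10 h (4.02). Muscle genes fell, among them Mlc1, a myosin light chain (-2.87 ± 0.35, adjusted p = 8.89e-04), and Tm2, a tropomyosin (-3.20 ± 0.42, adjusted p = 0.00134). CG12983 rose at least 86.3-fold, from the floor to 4101 ± 10.1, and Spp, a signal peptide peptidase, rose 2.89-fold (1.53 ± 0.19, adjusted p = 9.23e-04). In all 71 genes changed, 9 higher and 62 lower, with 230 without replicate 2 of the control and 37 without replicate 1 of the fragment group. Of 21 named calls 11 held without each array, and 8, 4, 6 and 5 were lost without replicates 1 and 2 of the control and of the fragment group. Replication fork genes had a median of -0.06 (camera adjusted p = 0.897). The stage index was -0.058, and 32 of the 71 genes had a deposited signal above 10000 on some array, against 3.2% of the genes tested.

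As lists with the E2f1 fragment, muscle markers (5 of 18 lower; 9 lower and 1 higher adjusted over the list alone, median -1.10) and epidermis and cuticle genes (2 of 23 lower, 5 adjusted over the list alone; -0.43) were lower, at camera adjusted p = 1.08e-05 and 5.37e-04, with adjusted p = 0.359 and 0.225 with an estimated correlation. Digestion genes (1 of 24 lower, median -0.60, adjusted p = 0.00307) and glycolysis genes (1 of 8 lower; -0.62, adjusted p = 0.00728) were also called lower, with adjusted p = 0.832 and 0.664 with an estimated correlation. Without replicate 2 of the control the 4 lists had adjusted p = 0.0594, 0.0803, 0.584 and 0.158. Digestion was also lost without replicate 1 of the fragment group (0.116) and glycolysis without replicate 2 (0.0821), where the epidermis median was -0.24. The digestion median was -1.03 without replicate 1 of the control. By fry the digestion and glycolysis calls were lost (adjusted p = 0.49 and 0.194).

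Expression of Rbf1 asks which genes respond to more of this E2F-binding protein. Rbf rose 7.14-fold (log2 change 2.84 ± 0.35, adjusted p = 4.82e-04). Genes of the ribosome fell: RpL32 fell from 18730 ± 2850 to 1612 ± 1400 (-3.87 ± 0.46, adjusted p = 3.71e-04), RpS18 by 2.31 on the log2 scale, and Rack1, a ribosome-bound scaffold protein, from 29440 ± 2900 to 3701 ± 2710 (-3.21 ± 0.33, adjusted p = 9.02e-05). The neuronal RNA-binding gene elav fell (-2.0 ± 0.35, adjusted p = 0.00866), a call lost without replicate 1 of Rbf1 (0.0736). In all 129 genes changed, 64 higher and 65 lower (49.6% higher), and 151 with the deposited scaling, 50 higher and 101 lower (33.1% higher). Of the 129 genes 54 were above 10000 in deposited signal on some array, and these arrays have the lowest upper percentiles. The count was 73 and 353 without replicates 1 and 2 of the control, and 81 and 47 without replicates 1 and 2 of Rbf1, whose E2f1 signals differ as given above. Of 20 named calls, 10, 3, 12 and 12 were lost without these arrays in turn. RpL3, RpL32, RpL40, RpS18, Rack1 and Rbf held without each.

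Ribosomal protein genes were the list with the smallest p in Rbf1 embryos (9 of 29 lower; 16 lower and 1 higher adjusted over the list alone, median -0.53, camera adjusted p = 5.18e-10, adjusted p = 0.126 with an estimated correlation). Of the 29 members 24 were above 10000 in deposited signal, with a median of -0.89. With such probe sets left out, an alternative added after seeing the data, 5 members remained, with a median of 0.05 (adjusted p = 0.943), so that value says nothing of the bright members. Over the list's alternatives the adjusted p ranged from 1.33e-21 to 0.943, and the median was -0.81 and -0.28 without replicates 1 and 2 of Rbf1. Replication fork genes were called lower (0 of 19 passed limma over all genes, 4 adjusted over the list alone, among them PolD2 at -1.55 ± 0.37, median -0.51, adjusted p = 3.56e-04, adjusted p = 0.95 with an estimated correlation), and without replicate 1 of the control the adjusted p was 0.408. Digestion genes were called lower (1 of 24 passed, median -0.75, adjusted p = 0.00736, adjusted p = 0.95 with an estimated correlation), and the call was lost without replicate 2 of the control (0.765) or of Rbf1 (0.328). The fork median was -0.91 without replicate 2 and the digestion median -1.14 without replicate 1 of the control. By fry both calls were lost (adjusted p = 0.29 and 0.589). Maternal markers, a set chosen after seeing the data, had a median of 0.75 (SD 0.58, 13 of 14 positive), with 1 that passed, smg, at 5197 ± 282 against 1532 ± 109.

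Loss of Dp asks which genes need the partner of both E2Fs. Digestive enzymes rose: betaTry, a trypsin, rose 27.4-fold, from 135.9 ± 19 to 3918 ± 1800 (log2 change 4.78 ± 0.53, adjusted p = 3.74e-04), and Jon65Aiv, a serine protease (3.70 ± 0.53, adjusted p = 0.00181), and Mal-A1, a maltase (2.69 ± 0.47, adjusted p = 0.0072), rose with it. PCNA fell 2.62-fold (-1.39 ± 0.20, adjusted p = 0.00166), and falls were also measured for dnk (-1.45 ± 0.21, adjusted p = 0.00233) and Dp itself, 3.2-fold (-1.68 ± 0.19). Nop60B, a pseudouridine synthase, fell at least 8.99-fold. In all 359 genes changed, 187 higher and 172 lower, with 84 and 785 without replicates 1 and 2 of the control and 71 without replicate 1 of the mutant. Of 45 named calls, 28, 4, 24 and 18 were lost without replicates 1 and 2 of the control and of the mutant. The 16 that held without each array include all genes named in this paragraph. The stage index was 0.249.

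In Dp mutants 13 of the 26 lists were called, among them several of differentiated tissues higher and the origin, mitosis and dREAM lists lower. Digestion genes (9 of 24 higher, 15 adjusted over the list alone, median 1.81, camera adjusted p = 3.38e-13, adjusted p = 0.095 with an estimated correlation) had the largest median. Heat shock and stress genes (3 of 13 higher, 7 adjusted over the list alone, median 0.81, adjusted p = 3.12e-05) were called also with an estimated correlation (adjusted p = 0.0217), with the glutathione transferase GstD1 at 1.49 ± 0.23. The sorter was used only for mutants of 8 to 10 h, so handling and genotype cannot be told apart for this list, here or in E2f1 mutants of that age (median 0.75). Muscle (median 0.85), immune (1.28), glycolysis (0.83), fat body (0.45), epidermis (0.53), glial (0.55) and haemocyte lists (0.33) were called higher, with 0, 1, 2, 1, 2, 1 and 1 members higher and adjusted p = 0.139, 0.095, 0.167, 0.0793, 0.139, 0.203 and 0.257 with an estimated correlation. On the epidermis list mwh (3.25 ± 0.63) and grh (1.06 ± 0.25) were higher and 1 member, dyl, was lower (-2.01 ± 0.50, adjusted p = 0.0362). These 3 calls were lost without replicate 1 of the control (0.0971, 0.114 and 0.14). Proteasome subunits (4 of 29 lower and 1 higher; 10 and 1 adjusted over the list alone, median -0.49, adjusted p = 3.45e-04), origin genes (2 of 19 lower; -0.61, adjusted p = 0.00229), mitosis genes (0 of 37 by limma, 6 lower adjusted over the list alone; -0.41, adjusted p = 0.00428) and dREAM subunits (2 of 10 lower, among them Dp; -0.40, adjusted p = 0.00428) were called lower, with adjusted p = 0.0939, 0.257, 0.456 and 0.139 with an estimated correlation. The DNA damage (adjusted p = 0.0951), replication fork (0.0984), neuronal (0.17), cohesion (0.329), tracheal (0.38), G1 and S (0.45), neuroblast (0.868) and nucleotide synthesis lists (0.962) were not called. Without replicate 1 of the control the origin, mitosis, epidermis and haemocyte lists were lost (adjusted p = 0.259, 0.773, 0.0681 and 0.622), without replicate 1 of the mutant the haemocyte and glycolysis lists (0.14 and 0.193), and without replicate 2 the glial list (0.161). The immune call was lost with the lowest 50% of probe sets left out (median 0.16, adjusted p = 0.295), the haemocyte call with no floor (0.0541) and the mitosis call by fry (0.156). Of the calls that were kept, the muscle, fat body and glial medians were 0.5, 0.22 and 0.26 without replicate 1 of the control, and the muscle median 0.17 without replicate 1 of the mutant. The fat body and haemocyte medians were 0.71 and 0.67 without replicate 2 of the control, and the heat shock and haemocyte medians 0.51 and 0.58 without replicate 2 of the mutant. With the control interpolated to the same stage index, 8 of the 13 calls were lost, those of the muscle, epidermis, haemocyte, glycolysis, origin, mitosis, dREAM and proteasome lists (adjusted p between 0.0943 and 0.929). For the muscle, epidermis, haemocyte and glycolysis lists, whose genes were not kept out of the index, this may be partly built in.

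Loss of E2f1 at 8 to 10 h asks which genes need the activating E2F. Replication genes fell: PCNA fell 4.57-fold (log2 change -2.19 ± 0.20, adjusted p = 2.81e-05) and dpa, a subunit of the MCM helicase also known as Mcm4, 6.66-fold (-2.74 ± 0.36, adjusted p = 9.35e-04). WRNexo, an exonuclease related to the Werner syndrome protein, fell 7.4-fold (-2.89 ± 0.30, adjusted p = 1.42e-04). Drsl5, a drosomycin-like peptide gene, fell 12.1-fold, from 11720 ± 3860 to 960.6 ± 255 (-3.59 ± 0.27, adjusted p = 1.02e-05). Cpr49Ac rose at least 16.3-fold from a control at the floor, a rise also called in other groups against that control, as given above. Mal-A1 rose (3.01 ± 0.47, adjusted p = 0.00311). In all 229 genes changed, 108 higher and 121 lower, with 77 and 748 without replicates 1 and 2 of the control and 56 without replicate 1 of the mutant. Of 34 named calls, 22, 1, 22 and 9 were lost without replicates 1 and 2 of the control and of the mutant, and 9 held without each array, among them all genes named in this paragraph. The stage index was 0.219.

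The 2 replication lists of E2f1 mutants kept their calls without each array, though the median of the origin list was -0.59 without replicate 1 of the control. Origin licensing and firing genes (7 of 19 lower, 12 adjusted over the list alone, median -1.27, camera adjusted p = 1.18e-10) and replication fork genes (5 of 19 lower, 13 adjusted over the list alone, 0 positive; -0.92, adjusted p = 8.27e-11) each had adjusted p = 0.0762 with an estimated correlation. Mitosis genes (1 of 37 lower and 36 negative, median -0.49, adjusted p = 1.42e-06, adjusted p = 0.227 with an estimated correlation) and heat shock genes (1 of 13 higher; 0.75, adjusted p = 3.35e-04, adjusted p = 0.0528 with an estimated correlation) also kept theirs. The mitosis median was -0.26 without replicate 1 of the control (adjusted p = 0.0338) and -0.91 without replicate 2. Of 12 nucleotide synthesis genes 3 fell: the thymidylate synthase Ts (-2.06 ± 0.40), RnrL (-1.56 ± 0.28) and dnk (-1.34 ± 0.21). That list was not called (adjusted p = 0.365). Ts and RnrL did not pass without replicate 1 of the control (0.129 and 0.094), nor Ts and dnk without replicate 1 of the mutant (0.121 and 0.0548). Cohesion (median -0.28), DNA damage (-0.42), dREAM (-0.36) and G1 and S lists (-0.26) were called lower, and haemocyte (0.57), digestion (0.59) and epidermis lists (0.50) higher, with adjusted p = 0.167, 0.174, 0.227, 0.271, 0.167, 0.368 and 0.227 with an estimated correlation. All 7 were lost without replicate 1 of the control (adjusted p = 0.136, 0.18, 0.253, 0.278, 0.163, 0.253 and 0.253). Without replicate 1 of the mutant the G1 and S list was lost (0.0943), and without replicate 2 the G1 and S, dREAM and epidermis lists (0.0716, 0.175 and 0.19). Without replicate 2 of the control the calls held and the G1 and S, dREAM, haemocyte, digestion and epidermis medians were -0.48, -0.57, 0.9, 0.97 and 0.31. The dREAM median was -0.55 without replicate 1 of the mutant and the cohesion median -0.45 without replicate 2. The epidermis call was also lost with the deposited scaling (0.0508), median centring (0.0502), no floor (0.0548), a replicate block (0.0521), the lowest 50% left out (0.182) and bright probe sets left out (0.201). The G1 and S call was lost with bright probe sets left out (0.0544) and, with the DNA damage call, with the lowest 50% left out (0.0628 and 0.284). The digestion call was lost by fry (0.18). With E2f1, E2f2, Dp and Rbf left out of the lists the G1 and S call was lost (median -0.23, adjusted p = 0.156) and the dREAM median was -0.58 (adjusted p = 0.0386). With the control interpolated to the same stage index, 6 of these 7 calls, all but the haemocyte list, were lost (adjusted p between 0.16 and 0.916).

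Direct comparison of the 2 mutants at 8 to 10 h asks where loss of E2f1 and loss of Dp differ. Relative to Dp mutants, E2f1 mutants had 26.8-fold less betaTry (138.3 ± 2.43 against 3918 ± 1800; log2 change -4.74 ± 0.53, adjusted p = 4.14e-04), less Drsl5 (-2.49 ± 0.27, adjusted p = 4.14e-04) and less Fmo-1, a flavin monooxygenase (-4.18 ± 0.49, adjusted p = 7.12e-04). They had at least 4.89-fold more Nop60B and more l(3)87Df (2.30 ± 0.29, adjusted p = 0.001). These calls held without each array. In all 89 genes differed, 38 higher and 51 lower, with 26 without replicate 1 of the Dp mutant and 13 without replicate 1 of the E2f1 mutant. Of 24 named calls, 14, 12, 18 and 8 were lost without replicates 1 and 2 of the Dp mutant and of the E2f1 mutant. Replication fork genes were lower in E2f1 mutants (1 of 19 passed, 9 adjusted over the list alone, median -0.80, camera adjusted p = 1.72e-08, adjusted p = 0.211 with an estimated correlation), as were origin genes (1 of 19, 7 adjusted over the list alone; -0.51, adjusted p = 5.7e-05, adjusted p = 0.295 with an estimated correlation) and DNA damage genes (2 of 23, 7 adjusted over the list alone; -0.27, adjusted p = 1.15e-05, adjusted p = 0.107 with an estimated correlation). Digestion (4 of 24 lower, median -0.77, adjusted p = 3.43e-06), muscle (-0.62, adjusted p = 1.6e-04) and immune lists (-0.30, adjusted p = 0.042) were called lower, each at adjusted p = 0.295 with an estimated correlation. The digestion median was -0.13 without replicate 1 of the Dp mutant (adjusted p = 0.0453), where the muscle list was lost (0.0984). The immune list was lost without replicate 2 of the Dp mutant (0.11) or replicate 1 of the E2f1 mutant (0.206). The immune call was also lost with a log2 offset of 50 (0.0545), no floor (0.0683), a replicate block (0.052), no filter on dim probe sets (0.238) and the lowest 50% left out (0.339). By fry the origin, muscle, digestion and immune calls were lost (adjusted p = 0.0691, 0.0967, 0.102 and 0.102). The DNA damage median was -0.5 without replicate 1 of the Dp mutant, and the digestion and muscle medians were -1.51 and -1.12 without replicate 2. Without replicate 2 of the E2f1 mutant the DNA damage and immune medians were -0.44 and -0.49.

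Loss of E2f1 at 14 to 16 h asks the same at the later age. Genes of mitosis fell: pim, the fly securin, fell 21.1-fold (log2 change -4.40 ± 0.24, adjusted p = 6.84e-08), the condensin subunit gene glu 13.2-fold (-3.72 ± 0.21, adjusted p = 6.84e-08), the cyclin gene CycB3 7.94-fold (-2.99 ± 0.25, adjusted p = 3.93e-06) and borr, a subunit of the chromosomal passenger complex, 33.9-fold (-5.08 ± 0.33, adjusted p = 2.95e-07), though another probe set of borr read -0.77. Some transcripts that mothers load into eggs fell as well: smg fell from 4226 ± 240 to 151.9 ± 43.7 (-4.83 ± 0.33, adjusted p = 4.93e-07) and bcd from 1150 ± 163 to 67.51 ± 28.3 (-4.15 ± 0.35, adjusted p = 3.73e-06). Proteases of the gut fell, such as betaTry (-4.26 ± 0.53, adjusted p = 2.01e-04), and Rrp46, of the RNA exosome, rose at least 4.75-fold. Neither E2f1 itself (-0.20, adjusted p = 0.912) nor PCNA (-0.69 ± 0.20, adjusted p = 0.0505) passed. In all 503 genes changed, 158 higher and 345 lower, with 203 and 332 without replicates 1 and 2 of the control and 252 without replicate 1 of the mutant. Of 42 named calls 25 held without each array, and 15, 12, 12 and 14 were lost without replicates 1 and 2 of the control and of the mutant.

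As lists in E2f1 mutants of 14 to 16 h, mitosis genes (19 of 37 lower and 1 higher; 22 and 1 adjusted over the list alone, median -1.20, camera adjusted p = 6.54e-16) and digestion genes (10 of 24 lower, 16 adjusted over the list alone; -1.95, adjusted p = 3.19e-12) were lower, each at adjusted p = 0.2 with an estimated correlation. The 14 measured maternal markers had a median of -1.08 (SD 1.73), with 11 negative and 4 that fell: bcd, smg, swa and plu. Origin genes were called lower (3 of 19, with dup, the fly Cdt1, at -2.17 ± 0.24, median -0.45, adjusted p = 0.00456, adjusted p = 0.482 with an estimated correlation), and replication fork genes were not called (adjusted p = 0.297). The origin median was -0.26 without replicate 2 of the control, and by fry that call was lost (adjusted p = 0.0596). Neuroblast markers were called higher (3 of 16, median 0.42, adjusted p = 0.0427, adjusted p = 0.2 with an estimated correlation), but not without replicate 1 of the control (0.123) or of the mutant (0.0953), nor with the deposited scaling (0.0689), median centring (0.103), a log2 offset of 50 (0.072) or no floor (0.0742). Over its alternatives the adjusted p ranged from 0.0177 to 0.2. Under median centring the median of all genes was 0.124 in this comparison.

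**Figure D3:**
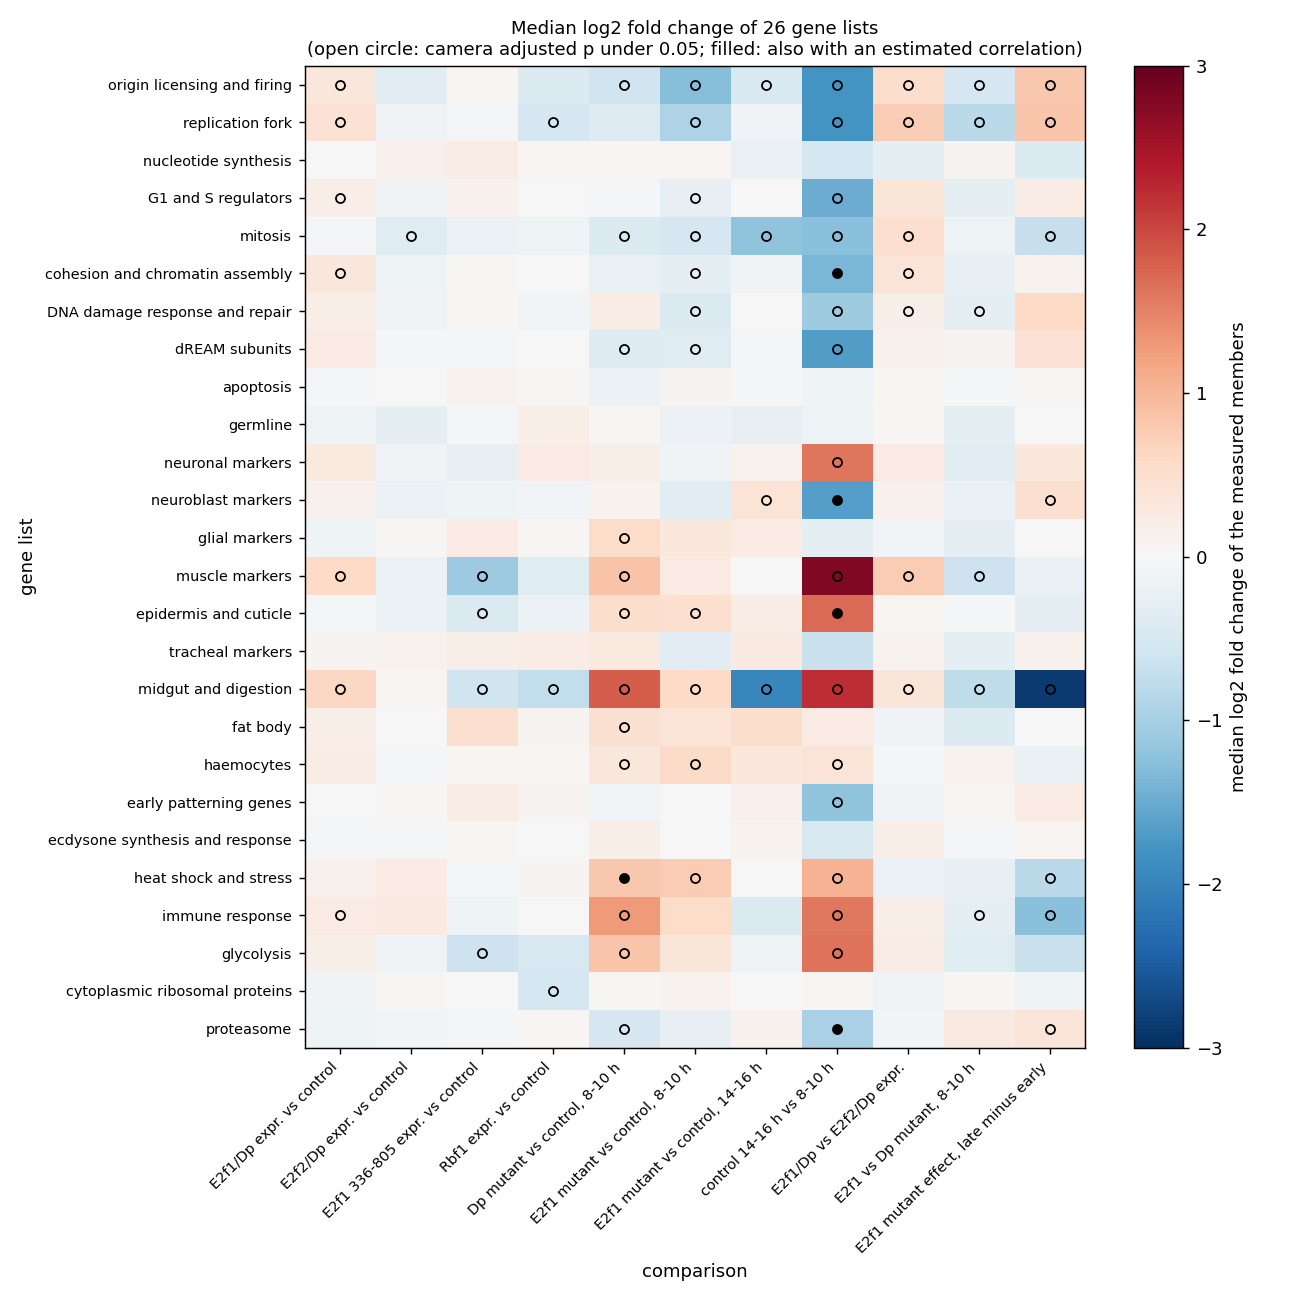
Median log2 fold change (colour scale from -3 to 3) of the measured members of 26 gene lists in 11 comparisons; open circles mark camera adjusted p under 0.05, filled circles lists called also with an estimated correlation. The digestion list stands at 1.81 in Dp mutants, -1.95 in E2f1 mutants of 14 to 16 h and 2.22 between the control ages, and the replication fork list at -0.92 in E2f1 mutants of 8 to 10 h.

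Whether the mutants share changed genes was compared across genes. Dp and E2f1 mutants at 8 to 10 h shared 55 genes higher and 34 lower, against 2.25 and 2.32 for independent calls, with 0 opposite by limma. PCNA and CG13794 fell and Mal-A1, RpL28 and RpL37A rose in both, and these calls held without each array. Both comparisons use the same 2 control arrays, which cannot be split and which the counts for independent calls do not allow for. The correlation across genes was 0.603 against 0.5 in simulations with no true change, and the covariance 0.2729 against 0.1084. The simulated correlation was about 0.5 for each pair with a shared control, and a control that varies more would raise it. The 8 to 10 h control had the lowest correlation between its arrays (0.894). Both mutants were also picked by the sorter and came from mutant stocks, not from the driver cross. Both had a higher stage index than the control (0.249 and 0.219). The overlap therefore cannot be read as a shared response to loss of E2f1 and Dp. E2f1 mutants at the 2 ages, with separate controls, shared 13 genes higher and 15 lower (1.9 and 4.65 for independent calls), with a correlation of 0.038 (simulated -0.004). Another 3 were higher at 8 to 10 h and lower at 14 to 16 h, and 4 the reverse (4.15 and 2.13 for independent calls), among them Cpr47Eb (2.81 and -2.17) and Drsl5 (-3.59 and 1.27). The E2f1 fragment and Rbf1 shared 8 lower genes and 1 higher (0.45 and 0.06 for independent calls), and 2 were higher with the fragment and lower with Rbf1 (0.07). They too share the control arrays. Their correlation of 0.519 was near the simulated 0.5, while their covariance was 0.1819 against a simulated 0.1082. The shared control was not split, so the excess over independent calls cannot be read as a shared response, nor is one excluded. E2f1/Dp and E2f2/Dp shared 1, Dp (correlation 0.387, simulated 0.5, and covariance 0.1089, simulated 0.1082). Of the genes higher in Dp mutants 27 were lower in E2f1 mutants at 14 to 16 h (7.19 for independent calls), among them betaTry and LysD. The stage index lay above the control in the Dp mutants (0.249 against 0) and below it in these E2f1 mutants (0.875 against 1), which was not separated from genotype. The reverse held for 6 genes (3.03), and 7 were higher and 14 lower in both (3.29 and 6.61).

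Whether the E2f1 mutant effect differs between the ages was tested as an interaction. The way mutants were picked and the direction of their difference in stage index from the control also changed between the ages. This contrast does not separate them. Drsl5 fell in the mutant at 8 to 10 h and read 1365 ± 270 against 572.3 ± 160 at 14 to 16 h (difference of log2 changes 4.86 ± 0.39, adjusted p = 1.59e-05). PCNA fell at 8 to 10 h and had a log2 change of -0.69 (adjusted p = 0.0505) at 14 to 16 h, a difference of 1.5 ± 0.28 (adjusted p = 0.00822), whereas pim (-4.13 ± 0.34, adjusted p = 1.59e-05) and bcd (-4.35 ± 0.50, adjusted p = 2.51e-04) had negative differences. These 2 fell at 14 to 16 h and did not pass at 8 to 10 h, with log2 changes of -0.27 (adjusted p = 0.601) and 0.2 (adjusted p = 0.818). In all 247 genes differed, 83 higher and 164 lower (33.6% higher); with median centring 135 were higher and 142 lower (48.7% higher), and the median of all genes was 0.136. The count was 538 without replicate 2 of the 8 to 10 h control, 132 without replicate 1 of the 8 to 10 h mutant, and 114 and 164 without replicate 1 of the 14 to 16 h control and mutant. Of 38 named calls 24 held without each array.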

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

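Of the tests in this part, those of maternal markers, of mitosis genes at 8 to 10 h and of one mutant against the other were chosen only after the result was seen, and the interpolation of the controls was an added alternative.

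The difference between E2f1 mutants and their control was not the same at 8 to 10 h and 14 to 16 h for 247 genes by the interaction in limma. Mutants were picked by a sorter at the first age and by hand at the second. Their stage index was 0.219 against 0 in the control at the first age and 0.875 against 1 at the second. An effect of E2f1 loss that depends on age, selection and stage therefore cannot be told apart in this contrast. The largest positive differences of log2 changes among named genes were those of Drsl5 (4.86), PolA2 (3.18), Mcm3 (3.06), Rrp46 (3.02), Su(Tpl) (2.93) and PIG-C (2.81), and CG13794 had 4.5. The largest negative ones were those of Jon99Fii (-6.15), Jon99Fi (-5.99), Jon44E (-5.82), Muc18B (-5.70), Jon66Ci (-5.47) and Hsp68 (-5.34), with CG10911 at -7.41 and CG10910 at -6.93. PolA2 and Rrp46 are at the floor in the 14 to 16 h control, and Jon66Ci and Hsp68 in the 14 to 16 h mutant, so their values depend on the floor.

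Among lists, the interaction was positive for replication fork genes (median 0.83, camera adjusted p = 9.68e-05, adjusted p = 0.35 with an estimated correlation), origin genes (0.80, adjusted p = 0.0295, adjusted p = 0.605 with an estimated correlation), neuroblast markers (0.47, adjusted p = 0.00912, adjusted p = 0.13 with an estimated correlation) and proteasome subunits (0.39, adjusted p = 0.0488, adjusted p = 0.359 with an estimated correlation). It was negative for digestion genes (-2.86, adjusted p = 5.73e-14, adjusted p = 0.138 with an estimated correlation), mitosis genes (-0.68, adjusted p = 1.17e-04, adjusted p = 0.45 with an estimated correlation), heat shock genes (-0.81, adjusted p = 0.0027, adjusted p = 0.121 with an estimated correlation) and immune genes (-1.25, adjusted p = 0.0136, adjusted p = 0.35 with an estimated correlation). Without replicate 1 of the 8 to 10 h control the origin, immune and proteasome calls were lost (adjusted p = 0.469, 0.152 and 0.189). Without replicate 2 of the 8 to 10 h mutant the immune and proteasome calls were lost (0.0823 and 0.201), without replicate 1 of the 14 to 16 h mutant the origin and proteasome calls (0.0844 and 0.161), and without replicate 2 of the 14 to 16 h control the proteasome call (0.133). The origin call was also lost with median centring (0.0515), no floor (0.0737), the lowest 50% left out (0.132) and by fry (0.163). The immune call was lost without a filter on dim probe sets (0.0743) and with the lowest 50% left out (0.132), and the proteasome call without that filter (0.208) and with bright probe sets left out (0.0512). The mitosis median was -0.33 without replicate 2 of the 8 to 10 h control, -0.44 without replicate 2 of the 14 to 16 h control and -0.28 without replicate 2 of the 14 to 16 h mutant. The heat shock median was -0.48 without replicate 1 of the 14 to 16 h control.

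Mitosis genes as a list and 4 of 14 maternal markers fell in E2f1 mutants at 14 to 16 h. Median log2 changes were -1.20 for the mitosis genes and -1.08 for the markers, of which 11 were negative and which had no list test. RNA of undeveloped eggs in the control collection could give this if picking the mutants by hand left such eggs out, which the labels do not say. Between the control ages smg (1.46) and bcd (1.19) were higher at 14 to 16 h, as such eggs would give, but the median of the 14 markers was 0.2 there (SD 0.94). The spread in the mutants was wide (SD 1.73), and the eggshell genes Vm26Aa and Cp36, chosen after their values were seen, read highest on replicate 1 of the mutant (3788 and 3309, against 667 and 540 on replicate 2). Loss of E2f1 as the cause also stays open: at 8 to 10 h, where maternal markers had a median of 0.16, the mitosis genes had a median of -0.49 (-0.26 without replicate 1 of the control). The explanations cannot be told apart here, because selection and genotype go together in every array of this age.

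Replication genes were lower in E2f1 mutants and digestion genes higher in Dp mutants at 8 to 10 h, and both mutants had a higher stage index than the control. For the replication genes an older age as the whole cause is argued against by the Dp mutants, which have a similar index. Against these the median was -0.76 (SD 0.69, 34 of 38 negative, camera adjusted p = 0.209 with an estimated correlation), and no course with age is assumed. Without single arrays the fork median there was -0.72 or lower and the origin median -0.35 or lower. With the control interpolated to the same stage index the median of the replication genes was -0.79 (SD 0.68, 36 of 38 negative, camera adjusted p = 1.39e-13, and adjusted p = 0.121 with an estimated correlation). That value assumes a linear course between 2 ages and alone excludes nothing. For the digestion genes the interpolated control gave a median of 1.23 (SD 0.97, 22 of 24 positive, camera adjusted p = 1.84e-08, and adjusted p = 0.211 with an estimated correlation), which goes against an older age as the whole cause and meets the bound set beforehand. An older age stays open all the same, since that bound assumed a linear course between 2 ages, and the median of 0.77 against E2f1 mutants (SD 1.18), which assumes none, rests on replicate 1 of the Dp mutant, the array of that group with the higher stage index (median -0.13 without it, E2f1 mutants minus Dp mutants). A part of either change may come from stage, and the effect of the genotype itself on the pace of development is not separated from it.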

How the results depend on the processing

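The alternatives with bright probe sets left out, with interpolated controls and with the manipulated genes left out of lists were chosen after seeing the data. No value of a named gene's own probe set reversed under the alternatives tried. Of 20 named calls whose gene has another probe set, 4 were opposite in sign on it: Tret1-1 with age (-1.14 against 0.47) and in E2f1 mutants at 14 to 16 h (0.88 against -0.02), CG32365 between E2f1/Dp and E2f2/Dp (-2.74 against 0.95) and borr in the interaction (-4.8 against 0.13). With single arrays left out, where a lone array is assumed to vary like the other groups, the counts ranged from 6 to 100 for E2f1/Dp, 3 to 194 for E2f2/Dp, 37 to 230 for the E2f1 fragment, 47 to 353 for Rbf1, 71 to 785 for the Dp mutant, 56 to 748 and 203 to 357 for the E2f1 mutant at 8 to 10 h and 14 to 16 h, 2837 to 3664 for control age, 9 to 74 for E2f1/Dp against E2f2/Dp, 13 to 107 for the E2f1 against the Dp mutant, and 114 to 538 for the interaction. Fitting the groups compared alone leaves fewer residual degrees of freedom, and gave 0 genes for E2f1/Dp in limma (767 at an unadjusted p under 0.05 in the fit of 18 arrays), 1 for E2f2/Dp, 1 for the fragment, 2 for Rbf1, 7 for the Dp mutant, 16 and 162 for the E2f1 mutant at the 2 ages, 6 for E2f1/Dp against E2f2/Dp, 3 for the E2f1 against the Dp mutant and 138 for the interaction. limma without the trend gave 39 for the fragment, 56 for Rbf1, 166 for the Dp mutant and 9 for E2f1/Dp against E2f2/Dp. Without a filter on dim probe sets the counts were 19 for E2f1/Dp, 15 for E2f2/Dp and 47 for the fragment. Median centring gave 16 for E2f1/Dp against E2f2/Dp and 59 for the E2f1 against the Dp mutant. For E2f1/Dp a log2 offset of 50 gave 13, a replicate block 5 and interpolated controls 14. Interpolated controls gave 42 for the fragment. With bright probe sets left out, which removes tested genes, the counts were 2 for E2f2/Dp, 24 for the fragment and 50 for Rbf1. Apart from the fits with fewer arrays or genes the cause was not tested. All other settings kept each count within 1.5 times. Of the named-gene values 385 were on the same side of the threshold with the deposited scaling (13 lost, 1 gained), 374 with median centring (24 lost, 1 gained), 331 without the trend (68 lost), 333 without a filter on dim probe sets (66 lost) and 211 with a fit of the groups compared alone (188 lost). With interpolated controls 122 were the same and 29 were lost. Of the camera list calls 77 were lost and 5 held with an estimated correlation, 25 were lost, 57 held and 10 were gained with fry, and 2 were lost and 13 gained with the deposited scaling. Signal over background limits 438 units that lie at the floor of 47.5 on all arrays of at least 1 group. A fold against such a group is a lower bound, and interaction values that include such a group depend on the floor.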

Other observations

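Of the tests in this part, that of bright genes in the deposited values was chosen only after the result was seen; the others were set before.

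In E2f1 mutants at 14 to 16 h, genes of chromatin assembly and of the cell cycle outside the mitosis list also fell. Caf1-55, a histone-binding protein of chromatin assembly and of the dREAM complex, fell by 2.90 on the log2 scale (SE 0.22, adjusted p = 1.09e-06), dUTPase, which removes dUTP, by 2.08 (SE 0.24, adjusted p = 7.8e-05) and the cyclin gene CycD by 1.33 (SE 0.21, adjusted p = 0.00125), and these calls held without each array. Their lists were not called there (camera adjusted p = 0.0756 for cohesion and chromatin assembly, 0.3 for nucleotide synthesis and 0.196 for G1 and S regulators). At this age selection by hand and genotype go together, so the explanations given for the mitosis genes cannot be told apart for Caf1-55, dUTPase and CycD either.

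Single ribosomal protein genes rose in both mutants of 8 to 10 h, while their list was not called in either (camera adjusted p = 0.17 in Dp and 0.136 in E2f1 mutants). The deposited signal exceeded by 0.1% of probe sets was 34606 to 46351 on these mutant arrays, against 23604 and 26047 on their control. Of the calls in Dp and E2f1 mutants 13.6% and 13.1% were above 10000 on some array, against 3.2% of the genes tested. Whether these rises follow array brightness was not tested. RpL28 rose by 1.19 ± 0.17 and 1.35 ± 0.17 and RpL37A by 1.97 ± 0.31 in each, on the log2 scale. The rise of RpL28 is not particular to the mutants: against the same control it also rose in E2f2/Dp embryos (1.39 ± 0.17) and with the E2f1 fragment (0.84 ± 0.17, adjusted p = 0.026, and 0.216 without replicate 2 of that group). RpL17 had 1.74 and 2.15 there and RpL37A -0.94 and -0.64, which did not pass. RpL17 read 25630 ± 3080 in Dp mutants, 28680 ± 1220 in E2f1 mutants, 1503 ± 652 in the control of that age, 77.41 ± 42.3 in Rbf1 embryos and rose with age in the control (log2 change 4.17 ± 0.73, adjusted p = 3.22e-04). Without replicate 1 of the control its rise in the mutants had adjusted p = 0.0734 and 0.0634, and without replicate 1 of the E2f1 mutant 0.0534.

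Ribosomal protein genes were lower on the Rbf1 arrays, which have the lowest upper percentiles of signal. In the deposited values genes of other functions above 20000 on the mutant arrays were also lower there (median log2 change -0.85, SD 0.24, 6 of 6 negative), while those between 2000 and 5000 had a median of 0.03, which is consistent with compression of the brightest probe sets on these arrays. After quantile normalization the bright genes of other functions had a median of 0.17, a value that met the bound set beforehand against compression, but that normalization fixes the upper end of every array, so the test is void. Lower ribosomal protein mRNA stays open beside it. Above 20000 the median was -1.24 for 21 ribosomal protein genes and -0.85 for the 6 genes of other functions, a difference of -0.39. The SD of single genes (0.97 and 0.24) does not measure the error of these medians, so the difference decides nothing.

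A hypothesis was that variants linked to the mutant chromosome add to the calls in Dp mutants, since Dp lies on chromosome 2. Between E2f1 and Dp mutants the odds ratio of a call on chromosome 2 against X was 1.79 (95% interval 0.88 to 4.03; p = 0.122, Fisher's exact test), and between Dp mutants and the control 1.76 (1.2 to 2.63; p = 0.00253, Fisher's exact test). The first interval includes 1, so linked variants may or may not add calls. For E2f1 mutants at 8 to 10 h against the control the odds ratio was 1.17 for chromosome 2 and 0.97 for chromosome 3. With the E2f1 fragment, which is no mutant, it was 3.64 for chromosome 3 (1.31 to 14.06; p = 0.00822, Fisher's exact test). These embryos hold an expression construct that the control cross lacks, so linked variants are not excluded there either. The ratio with the fragment therefore does not show what arises without linked variants. Fisher's exact test counts genes as independent, which genes of 1 family that fell with the fragment, such as TwdlN and TwdlL, need not be.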
